A study of Homo sapiens with 22 samples.

How the data were processed

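Per the labels, RNA was sequenced as stranded total RNA libraries (SMARTer kit) on a NextSeq 500 instrument. Stromal cells were of up to passage 10 at 70% confluency and had been fed 24 h before, and the labels give none of this for cardiomyocytes. The deposited notes give demultiplexing with bcl2fastq 2.20.0, alignment to hg19 with TopHat2 2.1.1 and counting with featureCounts 1.6.2, whereas the file headers name featureCounts 1.5.0-p2. Per the file headers the deposited unit is raw read counts per gene from featureCounts, counted over exons and joined by gene name, with both mates of a pair aligned and no strand option. Genes overlapping on opposite strands thus cannot be separated. The labels state a minimum of 25 M reads. Exon counts (25 M or more in 6 libraries, fewer in 16) leave out other reads and cannot test this.

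The 22 files held the same 26364 genes. Genes on the Y chromosome alone (106), XIST and TSIX were left out before any test, 108 in all. Coordinates are those of the files (hg19). Gene types came from a reference on GRCh38 and matched 25255 genes by name. No coordinate was taken from it. The files place 348 genes on several chromosomes. No pair of libraries had the same counts. The file headers name a run for both Cell Applications cardiac groups and another for the cardiomyocytes, and none for the remaining groups.

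Choices of groups, tests, gene lists, named genes and alternatives were made before the data were examined. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Genes were kept by filterByExpr with a minimum count of 10, which left 16207, and scaled by TMM (factors 0.722 to 1.187). A single quasi-likelihood fit with robust dispersion covered all 8 groups (common biological coefficient of variation 0.137). Each of 7 contrasts weighted its groups equally on the log scale. With several groups on a side, the sign of a log2 change can differ from that of mean CPM. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes with standard error (SE) are given where counts allow a fold change, and levels otherwise. The SE omits spread between populations. Log2 changes under alternatives have no SE and show direction only. Distances and principal components used log2 CPM with a prior count of 2.

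For each contrast, 24 gene lists fixed beforehand were tested with camera at its preset correlation of 0.01, adjusted over the lists. They covered sarcomere and contractile apparatus, calcium handling and electrical activity, heart-lineage transcription factors, structural matrix, matrix remodelling, smooth muscle and myofibroblast genes, mesenchymal and pericyte surface markers, HOX genes of paralogue groups 1 to 5 and of groups 6 to 13, cell cycle, pluripotency, fetal growth and imprinted genes, secreted growth factors and cytokines, interferon response, inflammatory chemokines and cytokines, cadherins with gap junctions and desmosomes, and fatty acid oxidation with muscle energy metabolism. Lists for other cell types were endothelial, epithelial and keratinocyte, neural and neural crest, blood and immune, skeletal muscle, mesothelial and epicardial, and bone, cartilage and fat. Members called higher or lower were counted after adjustment over all genes and, separately, adjusted over the list alone. Estimation of the correlation and the fry test were alternatives. Camera tests a list against the other genes, whereas fry tests it against no change.

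Named genes followed a rule. For each comparison they were the 8 called genes in each direction with the largest log2 change, no overlap between libraries of the sides and at least 5 CPM on the higher side. Small noncoding, uncharacterised and antisense genes, pseudogenes and sex-linked genes named above were not eligible. To these were added the first 3 members of each list described, in order of absolute log2 change (the rule allowed 4, and the limit of 3, applied to every list, was set after the data were seen), and 10 markers chosen beforehand (TNNT2, COL1A1, ACTA2, POSTN, TCF21, GATA4, TBX5, GJA1, PDGFRA and THY1). Some genes that the rule selects are not printed.

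Alternatives were DESeq2 size factors, no filter, the DESeq2 Wald test, fits of the compared groups alone, the replicate number as a block, each library left out in turn, other comparators, populations summed to a single replicate, and other prior counts and gene sets for distances. Alternatives added after the data were seen were cardiomyocytes without MTRNR2L genes, iPS-derived and cardiac comparisons within libraries with no run named, the cardiac comparison without Cell Applications adult cells, and all libraries thinned to the shallowest. The scripts were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. In the supplier comparison 93 and 100 were called in the right direction (12 unchanged genes called of 15365 tested). In the cardiac one 97 and 100 were (8 of 15390). False calls from differences between populations are not measured.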

Results

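RNA sequencing counts were compared across cultured human cells that are used to build engineered cardiac tissue. There were 22 libraries in 8 groups. Adult cardiac fibroblasts came from 2 suppliers, Cell Applications with 3 libraries and PromoCell with 3. Fetal cardiac fibroblasts from Cell Applications had 2 libraries, dermal fibroblasts 3, and mesenchymal stromal cells (MSCs) from bone marrow 2. Stromal cells grown out of a teratoma (a tumour of mixed tissues that pluripotent cells form) and out of embryoid bodies (aggregates of differentiating pluripotent cells) had 3 libraries each, both from the human induced pluripotent stem (iPS) line WTC11. Cardiomyocytes had 3 libraries and came from WTC11-GCaMP6f, a derivative of that line with a fluorescent calcium reporter.

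Total counts per library were 35999591 to 40512340 in adult cardiac fibroblasts from Cell Applications, 10001373 to 24332786 in those from PromoCell, 44072806 to 87140746 in fetal cardiac fibroblasts, 13003871 to 17066619 in dermal fibroblasts and 16392357 to 19766001 in marrow MSCs. They were 7678969 to 37779666 in teratoma outgrowth, 3461752 to 9387438 in embryoid body outgrowth and 6177971 to 6557414 in cardiomyocytes. Levels are given as counts scaled to library size (CPM), mean ± SD over the libraries of a group. A group listed at 0 had no count, which allows up to 0.0271 CPM in Cell Applications adult cardiac, 0.0566 in PromoCell adult cardiac, 0.0205 in fetal cardiac, 0.0714 in dermal, 0.09 in marrow MSC, 0.0442 in teratoma, 0.133 in embryoid body and 0.201 in cardiomyocyte libraries (3 counts over the group). Those limits cover counting error only. Adjusted p-values measure the spread between these libraries, and the labels do not say whether the libraries of a group came from separate donors or lots.

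Collagen, cardiac and mesenchymal markers separated the groups. COL1A1, a chain of type I collagen, stood at 14857 ± 1564 CPM in dermal fibroblasts and 12001 ± 90 in marrow MSCs, at 1109 to 4231 in the other stromal groups, and at 10.9 ± 4.8 in cardiomyocytes. GATA4, a cardiac transcription factor, was present at 12.4 to 38.5 CPM in the 3 cardiac fibroblast groups and 74 ± 3.4 in cardiomyocytes, and at 0.015 or less elsewhere. TBX5, another cardiac transcription factor, stood at 16.3 ± 0.77 CPM in fetal cardiac fibroblasts, 27.6 ± 2.1 in teratoma outgrowth and 61.4 ± 5.8 in cardiomyocytes. TCF21, a marker of epicardium-derived fibroblasts, ranged from 3.35 to 55.2 CPM in 6 stromal groups and had no count in marrow MSCs or cardiomyocytes. PDGFRA, a receptor of fibroblast progenitors, ranged from 8.66 to 704 CPM over the stromal groups, THY1 from 4.96 to 377, POSTN (periostin) from 319 to 6589, ACTA2 (smooth muscle actin) from 37 to 599 and GJA1 (connexin 43) from 429.6 to 1235.

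**Figure D1:**
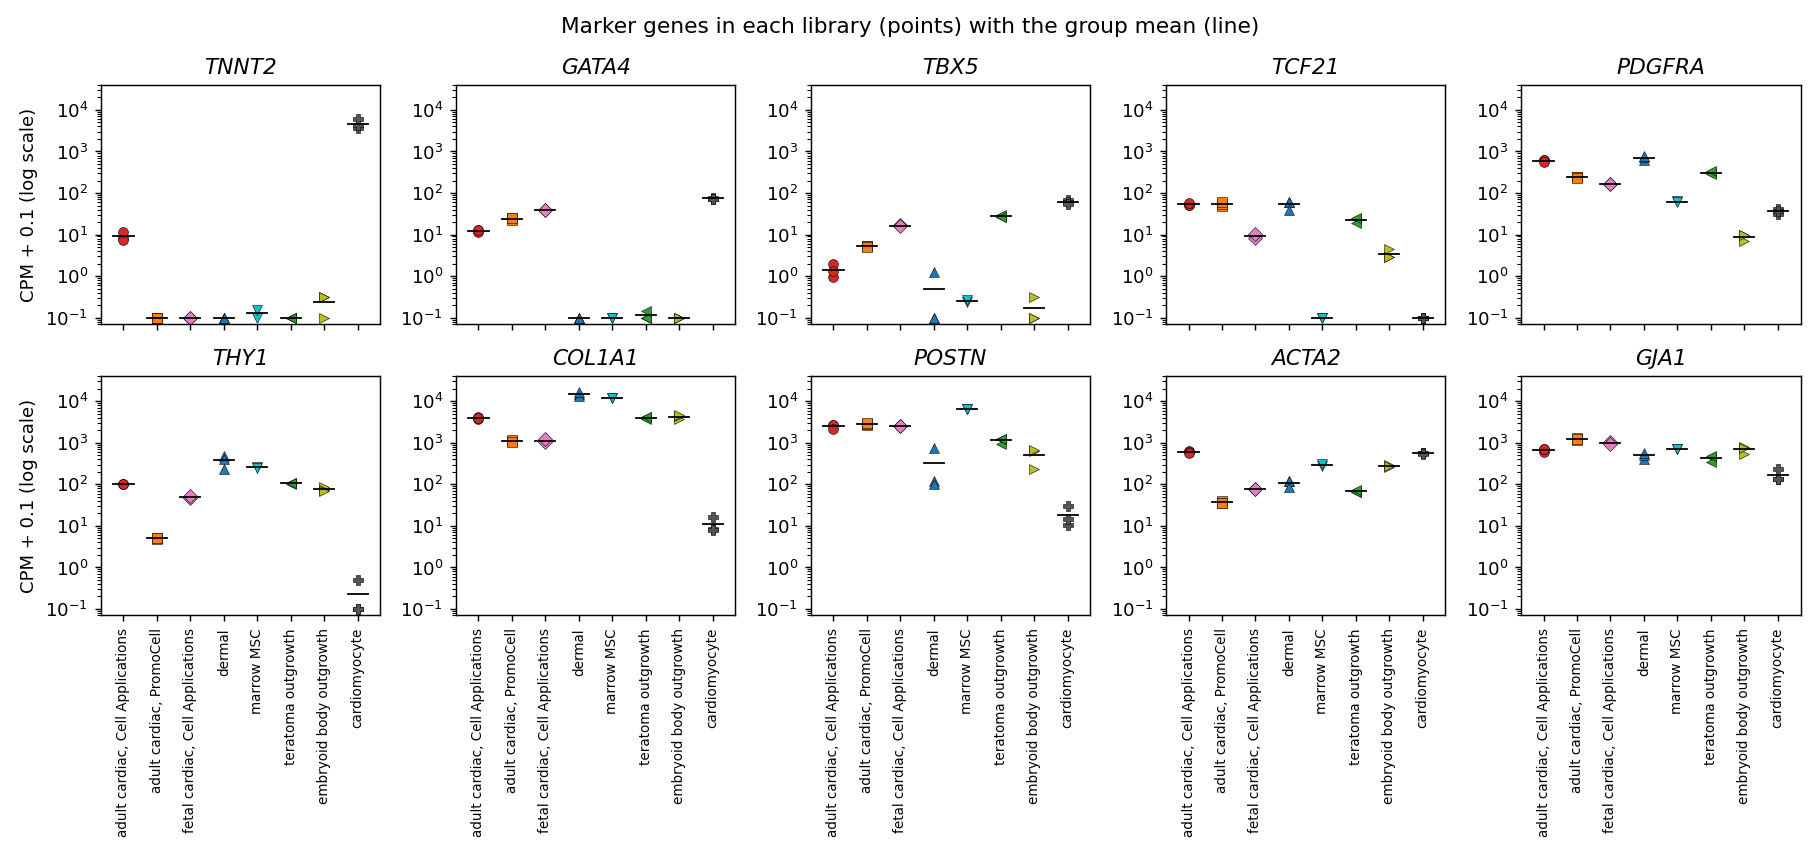
Marker genes by group, with CPM plus 0.1 on a log axis; each point is a library and each line a group mean. TNNT2 stood at 4698 ± 1265 CPM in cardiomyocytes and at 8.96 ± 2.3 in adult cardiac fibroblasts from Cell Applications, its highest stromal mean.

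Between libraries, the root mean square difference in log2 CPM per gene had a smaller median within every group (0.289 to 0.873) than between any pair of groups (0.949 to 2.814). Within Cell Applications adult cardiac fibroblasts it was 0.394 and within PromoCell ones 0.568. Adult cardiac fibroblasts of Cell Applications lay nearer to dermal fibroblasts (median 1.291) than to adult cardiac fibroblasts of PromoCell (1.411), and the ratio of the latter to the former was 1.093. Fetal cardiac fibroblasts lay nearer to those of PromoCell (0.949) than to those of Cell Applications (1.4), a ratio of 1.476, although they share supplier with the latter. The first principal component, 45.5% of the variance, set cardiomyocytes apart from the stromal groups.

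**Figure D2:**
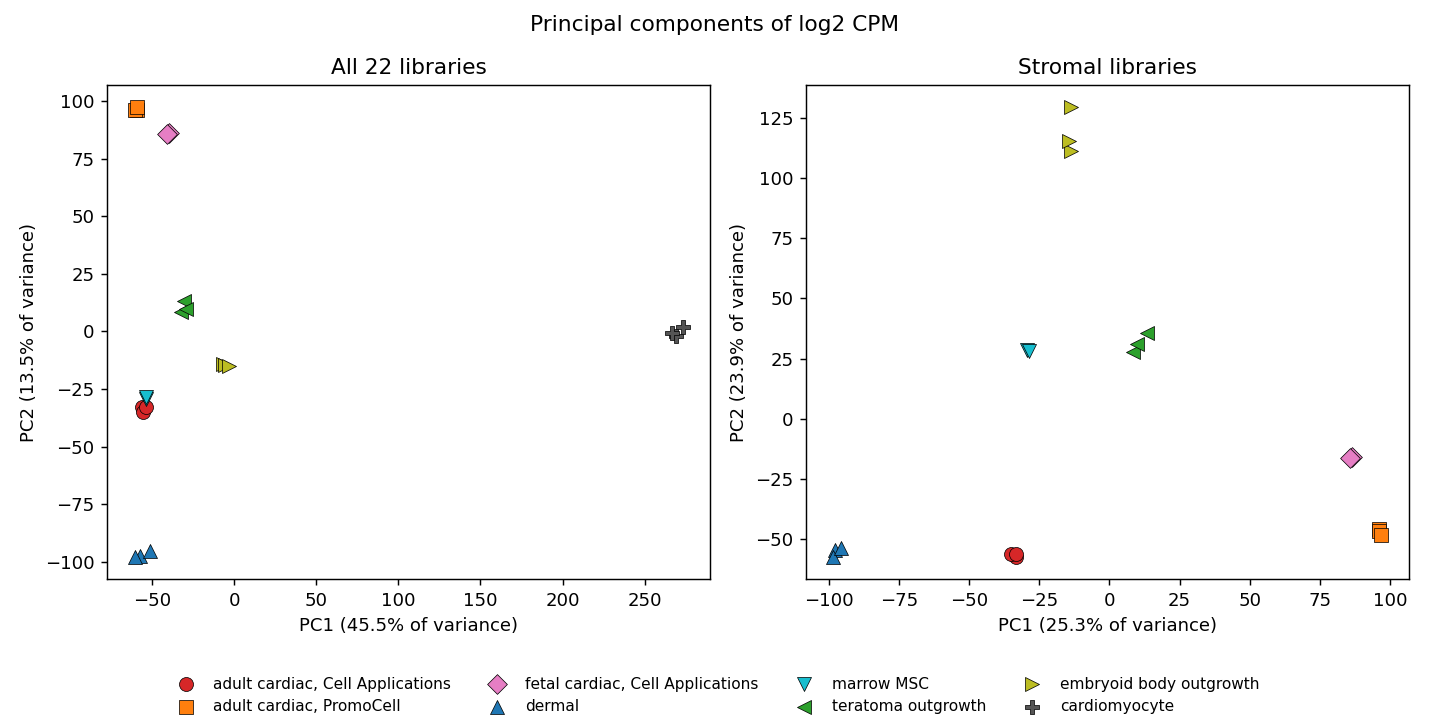
Principal components of log2 CPM for all 22 libraries (left) and for the stromal libraries alone (right), with the percent of variance on each axis and 1 symbol per library. Among stromal libraries, PromoCell adult and fetal cardiac fibroblasts lie together on the first component (25.3% of the variance), and Cell Applications adult cardiac fibroblasts lie on the side of dermal fibroblasts.

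Cardiomyocytes carried the transcripts of heart muscle contraction, and the stromal populations those of connective tissue. Of the genes of the sarcomere and contractile apparatus, 24 of 24 were higher in cardiomyocytes than in the mean of the 7 stromal groups (adjusted p = 5.63e-120). MYH7, the beta-myosin heavy chain (chromosome 14, 23881947 to 23904895 on hg19), stood at 7174 ± 1166 CPM and had no count in any stromal library. MYL7, an atrial myosin light chain, stood at 6894 ± 547 CPM against at most 0.0478 in a stromal group, and MYH6, the alpha-myosin heavy chain, at 1664 ± 332 against at most 0.0277. MYH6 and MYH7 are close paralogs, so the division of reads between them is uncertain.

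Genes of calcium handling and electrical activity were higher in 20 of 24 cases and lower in 2 (adjusted p = 2.01e-31). RYR2, the calcium release channel of heart muscle, stood at 1511 ± 66 CPM, TRDN, its partner triadin, at 1099.9 ± 89, and HRC, a calcium-binding protein of the sarcoplasmic reticulum, at 248 ± 47, against at most 0.0662, 0.482 and 0.0558 CPM in a stromal group. Heart-lineage transcription factors were higher in 16 of 20 cases and lower in 3 (adjusted p = 2.22e-10). HAND1 stood at 45.5 ± 3.7 CPM, NKX2-5 at 36.6 ± 2.5 and ISL1 at 29.8 ± 6.1, with stromal means of at most 0.00515, 4.64 (fetal cardiac) and 0.948. Genes of fatty acid oxidation and muscle energy metabolism were higher in 17 of 19 cases and lower in 2 (adjusted p = 3.13e-12). MB (myoglobin) stood at 42.9 ± 5.5 CPM, the nuclear receptor ESRRG at 110.5 ± 9.8 and COX6A2, a muscle subunit of cytochrome oxidase, at 10.1 ± 1.9, against stromal means of at most 0.105, 0.407 and 0. Genes of cadherins, gap junctions and desmosomes were higher in 12 of 22 cases and lower in 7 (adjusted p = 0.00107, adjusted p = 0.0841 with an estimated correlation). CTNNA3, an alpha-catenin of the intercalated disc, stood at 577 ± 43 CPM, CDH3 at 35.1 ± 4.4 and DSC2 (desmocollin 2) at 60.6 ± 10, against at most 0.144, 0.17 and 45.3. Skeletal muscle markers passed the test upward (adjusted p = 0.0275, adjusted p = 0.0669 with an estimated correlation) through 2 of 7 members. CKM (muscle creatine kinase) stood at 130.1 ± 14 CPM and ACTA1 (skeletal actin) at 44.4 ± 10, against at most 0.274 and 0.397, while the median log2 change of the list was -0.46 and the mean 1.47. Outside the lists, SMYD1, a muscle methyltransferase, stood at 971 ± 31 CPM, TECRL at 795 ± 52 and SPHKAP at 685 ± 76, against at most 0.0378, 0.00848 and 0.0548 in a stromal group.

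Matrix genes were among those lower in cardiomyocytes. GREM1, a secreted antagonist of bone morphogenetic proteins (chromosome 15, 33010205 to 33026870), ranged from 123 to 10469 CPM over the stromal groups, COL6A3 (a chain of type VI collagen) from 35.8 to 9556 and BGN (biglycan) from 107 to 446, and none had a count in cardiomyocytes. The same held for FAP (74.9 to 332 CPM), SRGN (35 to 297), DOCK10 (61.3 to 746), ITGBL1 (1.62 to 1368) and PTGS2 (4.45 to 1594). Structural matrix genes were lower in 33 of 38 cases and higher in 3 (adjusted p = 4.83e-14). COL1A2 stood at 1.53 ± 0.73 CPM against 874 to 12554. Matrix remodelling genes were lower in 26 of 29 cases and higher in 1 (adjusted p = 1.47e-14). LOX (lysyl oxidase) stood at 1.97 ± 1 CPM against 310.3 to 3851 and PLAT at 0.527 ± 0.41 against 40.4 to 2549.9. Mesenchymal and pericyte surface markers were lower in 17 of 20 cases and higher in 2 (adjusted p = 2.88e-10). ANPEP stood at 0 and NT5E (CD73) at 0.25 ± 0.28 CPM beside FAP. Inflammatory chemokines and cytokines were lower in 12 of 17 cases (adjusted p = 0.00334, adjusted p = 0.159 with an estimated correlation), with no cardiomyocyte count for PTGS2, CXCL1 or CXCL8. Secreted growth factors and cytokines were lower in 23 of 36 and higher in 9 (adjusted p = 0.0311, adjusted p = 0.186 with an estimated correlation), GREM1, CXCL8 and IL11 among the former. Cell cycle genes were lower in 27 of 30 cases (adjusted p = 0.00246, adjusted p = 0.619 with an estimated correlation). PLK1 stood at 3.92 ± 1.3 CPM, CDC20 at 2.37 ± 0.47 and RRM2 at 16.3 ± 1.8, and 7.3, 4.48 and 37.9 in embryoid body outgrowth, the lowest stromal means.

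The comparison asks what separates the muscle partner of an engineered tissue from its stromal partners. By the edgeR quasi-likelihood test, cardiomyocytes had 5652 genes higher and 6308 lower of 16207 tested, and 12 of 24 lists passed, 7 of them with an estimated correlation. The counts of these lists adjusted over the list alone were equal. No stromal header names the sequencing run of the cardiomyocytes, but 14 of the 19 stromal libraries name no run, so whether run changed with cell type is unknown. MTRNR2L genes took 27.3% ± 4.8 of cardiomyocyte counts and 1.29% to 3.32% (group means) of stromal counts, and DESeq2 size factors moved the median log2 change of all genes from -0.16 to 0.02. Calls of lists were lost (adjusted p) with no filter for skeletal muscle (0.199) and junction (0.129); with the replicate block for skeletal muscle (0.237) and junction (0.141); with libraries thinned to the shallowest (chosen after seeing the data) for skeletal muscle (0.0541), secreted factor (0.0541) and junction (0.0541). Calls were also lost against the outgrowths only for skeletal muscle (0.174) and junction (0.483).

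Stromal cells derived from iPS cells expressed more cell junction and fetal growth genes than the 5 primary stromal populations, and fewer matrix remodelling genes. Genes of cadherins, gap junctions and desmosomes were higher in 15 of 22 cases and lower in 3 (adjusted p = 1.02e-07). DSC2 (desmocollin 2) stood at 1.11 ± 0.21 CPM in teratoma and 45.3 ± 3.5 in embryoid body outgrowth against 0 to 0.78 over the 5 primary groups, DSG2 (desmoglein 2) at 149.5 ± 6.6 and 263 ± 7.9 against 0.535 to 102 (highest in fetal cardiac fibroblasts), and DSC3 at 10.7 ± 1.3 and 34.2 ± 6.5 against 0.127 to 24.6. Fetal growth and imprinted genes were higher in 9 of 15 cases and lower in 2 (adjusted p = 0.000104). LIN28B, an RNA-binding protein of embryonic cells, stood at 0.767 ± 0.11 and 1.68 ± 0.16 CPM against 0 to 0.0256, CDKN1C at 1 ± 0.4 and 0.791 ± 0.36 against 0 to 1.97, and MEST at 306 ± 39 and 47.1 ± 13 against 0.408 to 113. The comparison asks how stromal cells of stem cell origin differ from cells taken from tissue.

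Matrix remodelling genes were lower in 19 of 29 cases and higher in 5 (adjusted p = 3.6e-08). ADAMTS2, a procollagen peptidase, stood at 38.7 ± 3.7 CPM in teratoma and 0.739 ± 0.2 in embryoid body outgrowth against 11.9 to 364 over the 5 primary groups, MMP10 at 0.0444 ± 0.058 and 0.0685 ± 0.12 against 0.088 to 4.62, and CTSK (cathepsin K) at 4.13 ± 0.49 and 1.44 ± 0.54 against 5.72 to 32.6. Structural matrix genes were lower in 21 of 38 and higher in 7 (adjusted p = 3.25e-05, adjusted p = 0.197 with an estimated correlation). Of these, COL11A1 was higher (log2 change 4.79 ± 0.13 SE), while DCN (decorin) stood at 92.7 ± 25 and 0.488 ± 0.52 CPM against 15 to 733, and ELN (elastin) at 94.9 ± 14 and 0.0342 ± 0.059 against 0.779 to 1389. Mesenchymal and pericyte markers were lower in 10 of 20 and higher in 4 (adjusted p = 0.0368, adjusted p = 0.197 with an estimated correlation). Log2 changes were -5.12 ± 0.13 SE for ANPEP, 3.12 ± 0.09 for MCAM and -2.26 ± 0.08 for PDGFRA. Without dermal replicate 1 the adjusted p of that list was 0.0566. For teratoma outgrowth alone, ELN (log2 change 1.94) and PDGFRA (0.30) were higher.

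Interferon response genes were lower in 15 of 20 cases and higher in 2 (adjusted p = 2.96e-06, adjusted p = 0.0903 with an estimated correlation). OAS2, XAF1 and IFI44L stood at 0.0376 ± 0.065, 1.11 ± 0.096 and 0.263 ± 0.46 CPM in teratoma outgrowth and 0.0729 ± 0.13, 0.0365 ± 0.063 and 0.0685 ± 0.12 in embryoid body outgrowth, against 0.316 to 5.97, 1.68 to 36.3 and 0.596 to 14.2 over the 5 primary groups. Inflammatory chemokines and cytokines were lower in 11 of 17 cases and higher in 1 (adjusted p = 2.07e-06, adjusted p = 0.0575 with an estimated correlation). CXCL6 stood at 1.64 ± 0.58 and 0 CPM in teratoma and embryoid body outgrowth against 0.336 to 746 over the 5 primary groups, CXCL3 at 1.49 ± 0.62 and 0 against 1.23 to 73.7, and CXCL1 at 13.3 ± 2.6 and 1.81 ± 1.1 against 3.22 to 3129.7. Pluripotency genes were higher in 5 of 9 cases (adjusted p = 0.00582, adjusted p = 0.0575 with an estimated correlation), at low levels. SOX2 stood at 0.201 ± 0.19 and 1.99 ± 1.2 CPM against 0 to 0.042, DPPA4 at 0.507 ± 0.34 and 1.7 ± 0.63 against 0 to 0.0647, and L1TD1 at 3.02 ± 0.26 and 12.7 ± 3.9 against 0.296 to 1.13. Epithelial and keratinocyte markers were higher in 6 of 11 cases and lower in 1 (adjusted p = 0.0171, adjusted p = 0.173 with an estimated correlation). CLDN6 stood at 0.213 ± 0.25 and 0.141 ± 0.12 CPM against 0 to 0.0155 over the 5 primary groups. KRT8 (keratin 8) stood at 339.7 ± 29 and 167 ± 38 against 0.561 to 318 (highest in fetal cardiac fibroblasts), and KRT19 at 57 ± 6.6 and 38.3 ± 5.8 against 0.93 to 62.7 (highest in Cell Applications adult cells). Neural and neural crest markers were higher in 5 of 12 cases and lower in 1 (adjusted p = 0.0466, adjusted p = 0.197 with an estimated correlation), most in embryoid body outgrowth. S100B stood at 0.565 ± 0.44 CPM in teratoma and 18 ± 1.9 in embryoid body outgrowth, NGFR at 0.015 ± 0.026 and 68.2 ± 8.8, and NCAM1 at 5.5 ± 0.8 and 25.9 ± 8.7. Primary groups held 0 to 0.82, 0 to 0.0536 and 0.0544 to 58 CPM, NCAM1 being highest in fetal cardiac fibroblasts. The adjusted p of the neural list was 0.0606 without PromoCell adult cardiac replicate 3, 0.057 without its replicate 2, 0.0676 without dermal replicate 1, 0.0504 without marrow MSC replicate 2 and 0.137 without teratoma replicate 3. For NGFR the test without teratoma replicate 3 is void.

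Among single genes, SLITRK6, L1CAM, GABRA5, NLGN4X and COL9A3 were higher and stood at 40.7 ± 16, 155 ± 26, 65.2 ± 9.1, 17 ± 4.2 and 14.4 ± 1.2 CPM in embryoid body outgrowth but at 1.06, 7.83, 6.94, 1.39 and 0.359 in teratoma outgrowth. Their primary ranges were 0 to 0.046, 0 to 0.505, 0 to 2.07, 0 to 0.0925 and 0 to 0.0747. L1CAM is a neural adhesion molecule and GABRA5 a receptor subunit for the transmitter GABA. GFRA1, a receptor for glial cell line-derived neurotrophic factor, stood at 167 ± 7.5 CPM in teratoma and 178 ± 9.4 in embryoid body outgrowth against 0 to 66.3 over the 5 primary groups. POTEF stood at 22.6 ± 3 and 10.9 ± 2.3 CPM against 0 to 0.354, but it shares sequence with actin genes, so its counts are uncertain. Genes present in every primary group and near 0 in both outgrowths included ZNF736 (chromosome 7, 63774251 to 63817012; 14.2 to 22.7 CPM over the 5 primary groups, 0 in both), CHCHD2, a mitochondrial protein with processed pseudogenes (59.9 to 101 against 0.314 and 0.0729), and ZNF248 (11.4 to 19.5 against 0.122 and 0). ZNF736 and CHCHD2 also had no count in cardiomyocytes. ABCA6 stood at 0.038 and 0.0342 CPM in teratoma and embryoid body outgrowth, CTSF at 0.0301 and 0, AKR1C3 at 0.0534 and 0.109, ZNF37A at 1.03 and 0.221, and HIST1H1A at 1.53 and 0, against primary ranges of 2 to 56.3, 1.24 to 22.1, 3.58 to 67.4, 50.9 to 72 and 4.25 to 40.9 CPM.

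By the edgeR test, iPS-derived stromal cells had 3247 genes higher and 3289 lower of 16207 tested, and 10 of 24 lists passed, 3 of them with an estimated correlation. The counts adjusted over the list alone were 16 higher and 3 lower for cadherins, gap junctions and desmosomes, 10 higher and 2 lower for fetal growth and imprinted genes and 5 higher and 11 lower for mesenchymal and pericyte surface markers, and those of the other lists named here were equal. Within libraries whose headers name no run (chosen after seeing the data), 2959 genes were higher and 2582 lower. With libraries summed so that each population was 1 replicate, 1 gene was higher and 3 were lower (424 and 437 at unadjusted p under 0.05 of 16493), and 8 lists passed. A fit with 1 mean per side called 1395 genes, and 10 of the 21 groupings of 2 whole populations against 5, the real one included, called as many. Other fits lost calls of lists (adjusted p), with no filter for neural (0.0737); with DESeq2 size factors for neural (0.0543); with the replicate block for mesenchymal (0.109) and neural (0.109). They also lost calls with each population as 1 replicate for mesenchymal (0.203), epithelial (0.152) and neural (0.203); with libraries thinned to the shallowest (chosen after seeing the data) for mesenchymal (0.0758), pluripotency (0.153) and neural (0.238); with teratoma outgrowth alone for mesenchymal (0.716), pluripotency (0.108) and neural (0.328). Embryoid body outgrowth alone lost mesenchymal (0.0601) and epithelial (0.0509). Summing populations lost most named genes. DCN (0.118) and NGFR (0.826) lost calls (adjusted p) with teratoma outgrowth alone, and MEST (0.0945) with embryoid body alone. Thinning (likewise) lost CXCL6, MMP10 and NGFR in tests that may be void.

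In the mean of the 3 cardiac groups, cardiac transcription factors, endothelial markers and inflammatory cytokines were higher than in dermal fibroblasts and marrow MSCs. In this comparison cardiac levels are given in the order Cell Applications adult, PromoCell adult and fetal, and non-cardiac levels as dermal and then marrow MSC. GATA4 (chromosome 8, 11534428 to 11617511) stood at 12.4 ± 0.77, 24 ± 0.97 and 38.5 ± 0.79 CPM and had no count in dermal fibroblasts or MSCs. Heart-lineage transcription factors were higher in 10 of 20 cases and lower in 2 (adjusted p = 2.24e-05). WT1, a factor of the epicardium, stood at 0.402 ± 0.12, 36.3 ± 1.2 and 11.5 ± 0.57 against 0 and 0, and HEY2, a Notch target of the ventricle, at 2.48 ± 0.48, 36.1 ± 4.9 and 59.3 ± 7.5 against 0.157 ± 0.16 and 0. HOX genes, which record position along the body axis, were lower in that mean, in 13 of 14 cases for paralogue groups 1 to 5 (adjusted p = 7.57e-05) and 13 of 20 for groups 6 to 13 (adjusted p = 7.02e-05). Not every cardiac group lay below: HOXA3 stood at 0, 0 and 3.9 ± 0.54 CPM against 0.293 ± 0.45 and 2.64 ± 0.94 and HOXB5 at 0.0688 ± 0.096, 0 and 4.35 ± 0.37 against 0.482 ± 0.37 and 2.01 ± 0.43 (both chosen after their values were seen).

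HOXD8 stood at 1.79 ± 0.25, 0 and 0.0206 ± 0.029 CPM against 18.2 ± 3.4 and 14.4 ± 1.2, and HOXD9 had no count in the cardiac groups against 1.71 ± 0.57 and 0.886 ± 0.24. HOXD3, HOXD4 and HOXC5 stood at 4.02, 3.43 and 0.255 CPM in dermal fibroblasts, 0.528, 0.605 and 2.26 in MSCs and at most 0.0202, 0.323 and 0.088 in a cardiac group. HOXC10 had no cardiac count and stood at 0.0544 ± 0.094 and 28.2 ± 0.82. Without dermal replicate 1 its test is void. Endothelial markers were higher in 13 of 13 cases (adjusted p = 3.86e-14). CDH5 (VE-cadherin) stood at 1.07 ± 0.27, 74 ± 1.1 and 99.6 ± 5.5 CPM against 0.0957 ± 0.17 and 0, SOX17 at 0.44 ± 0.34, 40.1 ± 5.1 and 46.7 ± 1.5 against 0 and 0.132 ± 0.19 and ESAM at 1.4 ± 0.084, 0.252 ± 0.27 and 8.37 ± 0.38 against 0 and 0. PECAM1 stood at 1.65 ± 0.24, 47.7 ± 5.3 and 44.3 ± 0.52 CPM against 0.0816 ± 0.14 and 1.29 ± 0.043, and VWF, another endothelial gene, at 1 ± 0.38, 0.253 ± 0.14 and 0.244 ± 0.14 against 0.308 ± 0.36 and 0.0331 ± 0.047 (both chosen after their values were seen). VWF was not called without PromoCell replicate 3 (adjusted p = 0.0511), fetal cardiac replicate 3 (0.0688), dermal replicate 3 (0.0567) or marrow MSC replicate 1 (0.168). Inflammatory chemokines and cytokines were higher in 16 of 17 cases (adjusted p = 6.87e-17). Like CDH5, these were highest in PromoCell adult and fetal cells for IL1B (15.6 ± 2.8, 1356 ± 42 and 519 ± 0.69 CPM against 0.202 ± 0.13 and 0.127 ± 0.1) and CCL2 (109.8 ± 10, 812 ± 59 and 559 ± 59 against 29.8 ± 14 and 0.0274 ± 0.039). IL33 stood at 450.3 ± 64, 313 ± 11 and 63.2 ± 8.2 against 17.8 ± 7.3 and 0. Mesothelial and epicardial markers were higher in 7 of 10 cases and lower in 1 (adjusted p = 0.00531, adjusted p = 0.0595 with an estimated correlation). PODXL stood at 634 ± 3.1, 175 ± 16 and 354 ± 18 CPM against 101 ± 53 and 0.969 ± 0.13 and TCF21 at 53.7 ± 2.6, 55.2 ± 6.6 and 9.21 ± 1.2 against 53.9 ± 12 and 0. Against dermal fibroblasts alone, TCF21 was lower (log2 change -0.84).

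Structural matrix genes were lower in the mean of the cardiac groups in 28 of 38 cases and higher in 5 (adjusted p = 6.74e-17). FBLN5 (fibulin 5) had a log2 change of -4.70 ± 0.12 SE and TNC (tenascin C) of -4.45 ± 0.23, while MGP, an inhibitor of calcification, was higher, at 357 ± 47, 1.95 ± 0.88 and 7.25 ± 0.012 CPM against 1.32 ± 1.1 and 0.0549 ± 0.078. Mesenchymal and pericyte markers were lower in 16 of 20 cases and higher in 4 (adjusted p = 0.000266). Log2 changes were -4.72 ± 0.10 SE for PDGFRB, -3.40 ± 0.12 for THY1 and, upward, 5.07 ± 0.16 for the pericyte marker RGS5. PDGFRB stood at 64.3 CPM in Cell Applications adult cells but 2.38 in PromoCell ones. Matrix remodelling genes were lower in 18 of 29 and higher in 6 (adjusted p = 0.00102, adjusted p = 0.0595 with an estimated correlation). Among them MMP1 (interstitial collagenase) was higher, at 2384 ± 441, 4726 ± 255 and 272 ± 12 CPM against 13.9 ± 3 and 1.44 ± 0.49, as was MMP10 at 0.6 ± 0.14, 2.92 ± 0.75 and 4.62 ± 0.33 against 0.159 ± 0.086 and 0.088 ± 0.031. LOXL4 was lower at -3.42 ± 0.17 on the log2 scale, with cardiac levels of 37.7, 2.37 and 1.07 CPM. Smooth muscle and myofibroblast genes were lower in 12 of 17 cases and higher in 2 (adjusted p = 0.00107, adjusted p = 0.215 with an estimated correlation). Log2 changes were -3.46 ± 0.20 for LMOD1 and -2.61 ± 0.10 for MYLK, and LMOD1 stood at 18, 0.721 and 0.795 CPM in the cardiac groups. MYOCD (myocardin) was higher, at 41 ± 4.6, 54.3 ± 2.3 and 11.3 ± 0.16 CPM against 18.9 ± 0.7 and 0. Cell cycle genes were higher in 29 of 30 cases (adjusted p = 4.53e-10, adjusted p = 0.135 with an estimated correlation). Log2 changes were 1.20 ± 0.14 for CENPE, 1.19 ± 0.12 for CDC20 and 1.19 ± 0.17 for E2F1; CDC20 stood at 9.81 ± 1, 51.3 ± 1.7 and 61 ± 3.6 CPM against 16.1 ± 5.4 and 11.6 ± 0.73, with the Cell Applications adult mean below both. Cadherin and junction genes were higher in 12 of 22 cases and lower in 4 (adjusted p = 0.017, adjusted p = 0.16 with an estimated correlation). GJA5 (connexin 40) stood at 0.799 ± 0.13, 10.3 ± 1.5 and 8.56 ± 0.16 CPM against 0.0841 ± 0.15 and 0, CDH6 at 92.8 ± 3, 114 ± 1.4 and 364 ± 2.2 against 34 ± 3.5 and 0.694 ± 0.52 and CDH10 at 0.0829 ± 0.056, 4.19 ± 0.62 and 11.4 ± 0.52 against 0.0544 ± 0.094 and 0.165 ± 0.23. Epithelial markers were higher in 4 of 11 cases and lower in 1 (adjusted p = 0.0456, adjusted p = 0.18 with an estimated correlation; 0.055 without fetal cardiac replicate 2 and 0.0876 without marrow MSC replicate 2). KRT18 stood at 296 ± 24, 103 ± 12 and 161 ± 5.7 CPM against 10.6 ± 4.7 and 0.583 ± 0.26 and KRT8 at 20 ± 2, 19.8 ± 4.3 and 318 ± 6.3 against 7.38 ± 7.3 and 0.561 ± 0.14. CDH1 (E-cadherin) was called lower, at 1.77 ± 0.44, 0 and 0.0612 ± 0.00083 CPM against 1.33 ± 0.35 and 0.384 ± 0.54, and its log2 change was 0.01 without marrow MSC replicate 1.

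Of single genes, CD200, an immune checkpoint ligand, stood at 32.1 ± 1.7, 151 ± 5.5 and 100.5 ± 4.1 CPM against 0.0511 ± 0.045 and 0. VIPR1 stood at 2.19 ± 0.18, 18.5 ± 3.9 and 13.3 ± 0.97 and LYPD1 at 0.795 ± 0.13, 17 ± 2.2 and 23.2 ± 0.44, with no count in dermal fibroblasts or MSCs. CD93 stood at 1.29 ± 0.087, 6.69 ± 2 and 35.1 ± 1.3 and KCTD8 at 1.75 ± 0.48, 11.8 ± 1.1 and 12.4 ± 0.24, again without a count there. COMP, a cartilage matrix protein (chromosome 19, 18893583 to 18902114), stood at 449 ± 88 and 47 ± 0.032 CPM in dermal fibroblasts and MSCs against 3.89 ± 1, 0 and 0 in the cardiac groups. ENPP2 (autotaxin) stood at 342 ± 97 and 68.7 ± 0.47 against 37.9 ± 4, 0 and 0.122 ± 0.056. POU3F3, NRN1, TMEM119, ELFN2 and GFRA1 were also lower, at 3.48, 15.3, 50.4, 11.9 and 34.7 CPM in dermal fibroblasts, 129, 12.4, 104, 6.14 and 66.3 in MSCs, and at most 0.0206, 0.146, 6.04, 0.582 and 4.12 in a cardiac group.

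The comparison asks what tissue of origin leaves in cultured stromal cells. By the edgeR test, cardiac fibroblasts had 4345 genes higher and 3843 lower of 16207 tested, and 13 of 24 lists passed, 7 of them with an estimated correlation. Adjusted over the list alone, the counts were 12 higher and 2 lower for heart-lineage transcription factors and 5 higher and 29 lower for structural extracellular matrix, and those of the other lists named here were equal. Within libraries whose headers name no run (PromoCell adult cardiac against dermal and MSC, chosen after seeing the data), 3500 genes were higher and 3374 lower. With each population as 1 replicate, edgeR, the only tool run in that way, called 0 genes higher and 1 lower (762 higher and 610 lower at unadjusted p under 0.05 of 15789), and 12 lists passed. A fit with 1 mean per side called 2976 genes, and 3 of the 10 groupings of 3 whole populations against 2, the real one included, called as many. Calls of lists were lost (adjusted p) with no filter for epithelial (0.068); with the replicate block for epithelial (0.101) and junction (0.0534); with each population as 1 replicate for mesothelial (0.0661). Calls were also lost with libraries thinned to the shallowest (chosen after seeing the data) for HOX 1 to 5 (0.0592), mesothelial (0.0547) and junction (0.226); with no run named (likewise) for matrix remodelling (0.056) and epithelial (0.145); without Cell Applications adult cells (likewise) for epithelial (0.313). Calls were also lost with adult cardiac groups only for matrix remodelling (0.0613) and junction (0.0625); against dermal only for epithelial (0.399) and mesothelial (0.334); against MSC only for epithelial (0.151) and junction (0.205). Summing populations lost calls of most named genes. VWF lost its call (adjusted p) with DESeq2 (0.0563) and without Cell Applications adult cells (likewise, 0.185). Thinning (likewise) lost HOXB5 (0.281) and, in tests that may be void, CDH10, ESAM and HOXC10. Against dermal only, HOXA3 (0.0503) and VWF (0.66) lost calls, and against MSC only, CDH1 (0.0603).

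Dermal fibroblasts and marrow MSCs differed in HOX genes of the higher paralogue groups. HOX genes of paralogue groups 6 to 13 were lower in dermal fibroblasts in 13 of 20 cases and higher in none (adjusted p = 6.63e-05). HOXC10 stood at 0.0544 ± 0.094 CPM in dermal fibroblasts and 28.2 ± 0.82 in MSCs, HOXC11 at 0.0272 ± 0.047 and 3.11 ± 0.099, and HOXA9 at 0 and 0.876 ± 0.54. HOX genes of groups 1 to 5 were lower in 9 of 14 and higher in 3 (adjusted p = 0.0233, adjusted p = 0.223 with an estimated correlation). HOXA3 stood at 0.293 ± 0.45 and 2.64 ± 0.94 CPM, and HOXD1 was higher in dermal fibroblasts at 1.16 ± 0.51 against 0. Interferon response genes were higher in dermal fibroblasts in 10 of 20 cases and lower in 1 (adjusted p = 0.0013, adjusted p = 0.223 with an estimated correlation). IFIT2 stood at 10.5 ± 0.47 CPM against 0.424 ± 0.056. Log2 changes were 3.65 ± 0.34 SE for XAF1 and 3.60 ± 0.36 for IFITM1.

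Several single genes were present in dermal fibroblasts and without a count in MSCs. Of these, ACAN (aggrecan, chromosome 15, 89346674 to 89418585) stood at 463 ± 354 CPM, the integrin ITGA8 at 333 ± 91 and the growth factor PDGFD at 73.9 ± 24. PI16 stood at 73.4 ± 3.6, TCF21 at 53.9 ± 12, the cytokine receptor subunit CSF2RB at 49.9 ± 28 and the transcription factor GATA2 at 47.7 ± 20. FBLN2 (fibulin 2) stood at 635 ± 127 CPM against 0.0823 ± 0.12. In MSCs, the adhesion molecule CADM3 (chromosome 1, 159141377 to 159172932) stood at 186 ± 20 CPM, the chemokine receptor ACKR1 at 16.2 ± 2.8, SLITRK4 at 6.99 ± 0.9, ITGB6 at 6.27 ± 0.95, RNF128 at 6.11 ± 0.34 and the hyaluronan synthase HAS1 at 5.78 ± 0.34, none with a count in dermal fibroblasts. ST6GAL2, a sialyltransferase, stood at 48.9 ± 3.3 CPM in MSCs and 0.0482 ± 0.043 in dermal fibroblasts.

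The comparison sets the non-cardiac primary populations against each other. By the edgeR test, dermal fibroblasts had 3681 genes higher and 3523 lower of 16207 tested, and 3 of 24 lists passed, 1 of them with an estimated correlation. For these lists the counts adjusted over the list alone were equal. The number of lists was 7 without dermal replicate 1, 6 without dermal replicate 2, 5 with no filter on low counts and 8 when these groups alone were fitted, of which 2 were among the 3. Dermal replicate 1 stood apart from replicates 2 and 3 (chi-square per degree of freedom 58.5 and 54.6, against 14.7 between those). Other fits lost calls of lists (adjusted p), with these groups alone for HOX 1 to 5 (0.0636); with libraries thinned to the shallowest (chosen after seeing the data) for HOX 1 to 5 (0.0598). Other fits lost calls of genes (adjusted p), with DESeq2 for HOXA3 (0.139) and HOXA9 (0.462). No run is named in the headers of these libraries.

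Fetal cardiac fibroblasts had more transcripts of cardiac transcription factors, endothelial markers and inflammatory cytokines, and fewer of matrix and smooth muscle genes, than adult cardiac fibroblasts of the same supplier. Levels are given as fetal against Cell Applications adult, with the PromoCell adult mean in parentheses, all in CPM. Heart-lineage transcription factors were higher in 13 of 20 cases and lower in 3 (adjusted p = 6.32e-06). GATA5 stood at 1.27 ± 0.26 against 0 (PromoCell 0), NKX2-5 at 4.64 ± 0.53 against 0.0453 ± 0.043 (PromoCell 0) and IRX4, a ventricular factor, at 0.984 ± 0.15 against 0.0177 ± 0.015 (PromoCell 0). Endothelial markers were higher in 11 of 13 cases and lower in 1 (adjusted p = 2.46e-11). KDR, a receptor for vascular endothelial growth factor, stood at 374 ± 6.2 against 0.914 ± 0.56 (PromoCell 219), TIE1 at 75.1 ± 3.3 against 0.264 ± 0.093 (PromoCell 21.6) and SOX17 at 46.7 ± 1.5 against 0.44 ± 0.34 (PromoCell 40.1). Inflammatory chemokines and cytokines were higher in 13 of 17 cases and lower in 2 (adjusted p = 6.33e-08). IL1A stood at 201 ± 19 against 1.4 ± 0.38 (PromoCell 636), CXCL6 at 307 ± 6.1 against 6.41 ± 2.3 (PromoCell 746) and CSF3 at 3.9 ± 0.091 against 0.0812 ± 0.073 (PromoCell 132).

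Structural matrix genes were lower in 30 of 38 cases and higher in 4 (adjusted p = 1.36e-10). ELN (elastin) stood at 2.08 ± 0.05 against 473 ± 15 (PromoCell 0.779), COL15A1 at 0.436 ± 0.35 against 52.9 ± 11 (PromoCell 0.476) and MGP at 7.25 ± 0.012 against 357 ± 47 (PromoCell 1.95). Matrix remodelling genes were lower in 18 of 29 cases and higher in 6 (adjusted p = 1.61e-05). ADAMTS8 stood at 0 against 0.349 ± 0.38 (PromoCell 0), LOXL4 at 1.07 ± 0.21 against 37.7 ± 13 (PromoCell 2.37) and PLAT (tissue plasminogen activator) at 136 ± 7.1 against 2549.9 ± 159 (PromoCell 539). Smooth muscle and myofibroblast genes were lower in 15 of 17 cases and higher in 1 (adjusted p = 5.78e-08). MYH11, smooth muscle myosin, stood at 0.896 ± 0.33 against 32.3 ± 4.8 (PromoCell 1.42), LMOD1 at 0.795 ± 0.1 against 18 ± 0.58 (PromoCell 0.721) and CNN1 (calponin 1) at 5.93 ± 0.016 against 66.8 ± 1.4 (PromoCell 2.44). Mesenchymal and pericyte markers were lower in 15 of 20 cases and higher in 3 (adjusted p = 6.32e-06). S100A4 stood at 2.05 ± 0.47 against 34.3 ± 12 (PromoCell 12) and CD248 at 121 ± 3 against 713 ± 13 (PromoCell 16.7), while VCAM1 was higher at 6.91 ± 0.99 against 0.0454 ± 0.058 (PromoCell 2.71). HOX genes of groups 1 to 5 were higher in 10 of 14 cases and lower in 1 (adjusted p = 0.00147). HOXA3 stood at 3.9 ± 0.54 against 0 (PromoCell 0), HOXA5 at 1.04 ± 0.065 against 0 (PromoCell 0) and HOXB5 at 4.35 ± 0.37 against 0.0688 ± 0.096 (PromoCell 0). Cell cycle genes were higher in 28 of 30 cases (adjusted p = 2.46e-11, adjusted p = 0.0887 with an estimated correlation). KIF20A stood at 79.7 ± 0.84 against 10.8 ± 1.8 (PromoCell 73.6), CDC20 at 61 ± 3.6 against 9.81 ± 1 (PromoCell 51.3) and PLK1 at 87.4 ± 6.2 against 15.3 ± 3.2 (PromoCell 109).

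Genes of fatty acid oxidation and muscle energy metabolism were lower in 8 of 19 cases and higher in 2 (adjusted p = 0.0135). The fatty acid transporter CD36 stood at 0.0206 ± 0.029 against 216 ± 19 (PromoCell 0) and PDK4 at 0.204 ± 0.055 against 5.85 ± 1.2 (PromoCell 0.483), and ESRRG was higher at 0.305 ± 0.11 against 0 (PromoCell 0.407). Sarcomere genes were lower in 9 of 24 cases and higher in 2 (adjusted p = 0.0278, adjusted p = 0.0887 with an estimated correlation). TNNT2 stood at 0 against 8.96 ± 2.3 (PromoCell 0), XIRP1 at 0.0103 ± 0.015 against 1.83 ± 0.21 (PromoCell 0) and CRYAB, a small heat shock protein, at 2.1 ± 0.74 against 185 ± 54 (PromoCell 2.57). Interferon response genes were lower in 15 of 20 cases and higher in 2 (adjusted p = 3.68e-05, adjusted p = 0.0709 with an estimated correlation). BST2 stood at 0.0567 ± 0.08 against 4.99 ± 1.1 (PromoCell 0.231), IFIT2 at 1.62 ± 0.45 against 22.3 ± 2.6 (PromoCell 2.61) and IFI27 at 0.336 ± 0.13 against 3.39 ± 0.7 (PromoCell 5). Cadherin and junction genes were higher in 13 of 22 and lower in 8 (adjusted p = 0.00775, adjusted p = 0.0887 with an estimated correlation). DSC2 stood at 0.78 ± 0.16 against 0 (PromoCell 0), CDH10 at 11.4 ± 0.52 against 0.0829 ± 0.056 (PromoCell 4.19) and DSC3 at 24.6 ± 1.2 against 0.824 ± 0.22 (PromoCell 0.158). Of single genes, CCNA1 (cyclin A1) stood at 54.4 ± 0.21 against 0.00922 ± 0.016 (PromoCell 6.08), MDFI at 14.6 ± 0.18 against 0 (PromoCell 2.04) and MMRN1 at 12.3 ± 0.63 against 0 (PromoCell 0). Likewise higher were PPP1R16B at 6.92 ± 0.23 against 0 (PromoCell 0.645), VAT1L at 17 ± 1.1 against 0.00848 ± 0.015 (PromoCell 0.0496) and ADD2 at 14.3 ± 1.2 against 0.00922 ± 0.016 (PromoCell 0.194). MMRN1 (multimerin 1) is made by platelets and endothelium. On the lower side were TRH (thyrotropin-releasing hormone, chromosome 3, 129693236 to 129696781) at 0 against 274 ± 53 (PromoCell 0), MEOX2 at 0 against 87.8 ± 3.9 (PromoCell 0.0744), IGFBP1 at 0 against 59.7 ± 13 (PromoCell 0.259) and KRT14 at 0.0361 ± 0.051 against 431 ± 52 (PromoCell 0.421). So were A2M at 0.0153 ± 0.007 against 113 ± 9.7 (PromoCell 0.0248), ITGA8 at 0.0309 ± 0.044 against 222 ± 17 (PromoCell 0.0472) and the imprinted RNA H19 at 0.0404 ± 0.057 against 121 ± 15 (PromoCell 0).

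The comparison asks what stage of development adds within cardiac fibroblasts of a single supplier, whose libraries also shared a sequencing run. By the edgeR test, fetal cells had 3979 genes higher and 4066 lower of 16207 tested, and 13 of 24 lists passed, 9 of them with an estimated correlation. Adjusted over the list alone, the counts were 6 higher and 19 lower for matrix remodelling enzymes and inhibitors and 13 higher and 9 lower for cadherins, gap junctions and desmosomes, and those of the other lists named here were equal. Against PromoCell adult fibroblasts, 2069 genes were higher and 1600 lower, 1044 and 935 of them shared with the comparison above, and 8 lists passed. There the inflammatory list was lower in fetal cells (adjusted p = 9.26e-15) and the mesenchymal list higher (adjusted p = 0.0132), and ELN, MGP, CNN1, CD248, IL1A and CSF3 were called in the other direction. Against the mean of both adult groups 3161 genes were higher and 2636 lower, and 11 lists passed, 9 of them among the 13. Calls of lists were lost (adjusted p) with these groups alone for sarcomere (0.057); with the replicate block for sarcomere (0.051), junction (0.0855) and fatty acid (0.051); with libraries thinned to the shallowest (chosen after seeing the data) for sarcomere (0.2). Calls were also lost against PromoCell for sarcomere (0.812), heart-lineage (0.217), structural matrix (0.369), smooth muscle (0.585), cell cycle (0.812) and fatty acid (0.812); against both adult groups for sarcomere (0.743), mesenchymal (0.139), inflammatory (0.121) and fatty acid (0.203). Calls of genes were lost (adjusted p) with DESeq2 for GATA5 (0.302); with libraries thinned (likewise) for ADAMTS8 (0.189) and ESRRG (0.0879); against PromoCell for A2M, ADAMTS8, BST2, CDC20, COL15A1, CRYAB, IFIT2, ITGA8, KIF20A, KRT14, LMOD1, MEOX2, MYH11, PDK4, SOX17, TNNT2, TRH and VCAM1. Calls were also lost against both adult groups for ADAMTS8, CD36, CSF3, H19, TNNT2, TRH and XIRP1.

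Adult cardiac fibroblasts of the 2 suppliers differed in inflammatory, endothelial, mesenchymal and heart-lineage genes. Inflammatory chemokines and cytokines were lower in Cell Applications cells in 16 of 17 cases (adjusted p = 5.44e-18). In CPM and as Cell Applications against PromoCell, CSF3 (granulocyte colony-stimulating factor, chromosome 17, 38171614 to 38174066) stood at 0.0812 ± 0.073 against 132 ± 10, IL1A at 1.4 ± 0.38 against 636 ± 39 and CXCL6 at 6.41 ± 2.3 against 746 ± 37. Endothelial markers were lower in 8 of 13 and higher in 4 (adjusted p = 0.000626). KDR stood at 0.914 ± 0.56 against 219 ± 5.7, SOX17 at 0.44 ± 0.34 against 40.1 ± 5.1 and TIE1 at 0.264 ± 0.093 against 21.6 ± 2.5. Mesenchymal and pericyte surface markers were higher in 15 of 20 cases and lower in 1 (adjusted p = 2.95e-09). CD248 stood at 713 ± 13 against 16.7 ± 3.8 and PDGFRB at 64.3 ± 0.66 against 2.38 ± 0.32, and VCAM1 was lower at 0.0454 ± 0.058 against 2.71 ± 1.1. Heart-lineage transcription factors were lower in 9 of 20 and higher in 2 (adjusted p = 0.00118). WT1 stood at 0.402 ± 0.12 against 36.3 ± 1.2 and HEY2 at 2.48 ± 0.48 against 36.1 ± 4.9.

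Structural matrix genes were higher in Cell Applications cells in 29 of 38 cases and lower in 4 (adjusted p = 6.21e-10, adjusted p = 0.0612 with an estimated correlation). ELN stood at 473 ± 15 against 0.779 ± 0.5, MGP at 357 ± 47 against 1.95 ± 0.88 and COL15A1 at 52.9 ± 11 against 0.476 ± 0.17. Smooth muscle and myofibroblast genes were higher in 14 of 17 cases and lower in 2 (adjusted p = 9.81e-09, adjusted p = 0.0612 with an estimated correlation). Log2 changes were 4.76 ± 0.32 SE for CNN1, 4.67 ± 0.54 for ACTG2 and 4.47 ± 0.34 for LMOD1. Matrix remodelling genes were higher in 16 of 29 cases and lower in 6 (adjusted p = 0.0225, adjusted p = 0.178 with an estimated correlation). ADAMTS8 stood at 0.349 ± 0.38 against 0, LOXL4 at 37.7 ± 13 against 2.37 ± 0.54 and ADAMTS5 at 46.2 ± 4.1 against 6.25 ± 0.41. Genes of fatty acid oxidation and muscle energy metabolism were higher in 7 of 19 cases and lower in 2 (adjusted p = 0.0325, adjusted p = 0.0612 with an estimated correlation). CD36 stood at 216 ± 19 against 0 and FABP3 at 20.2 ± 3.9 against 0.607 ± 0.19, and ESRRG was lower at 0 against 0.407 ± 0.28. Cell cycle genes were lower in 28 of 30 cases (adjusted p = 2.8e-13, adjusted p = 0.101 with an estimated correlation). Log2 changes were -2.83 ± 0.23 SE for PLK1, -2.76 ± 0.19 for KIF20A and -2.47 ± 0.22 for MKI67, a marker of dividing cells. The endothelial markers named above were lower in the same libraries. Epithelial and keratinocyte markers were higher in 6 of 11 cases (adjusted p = 0.0282, adjusted p = 0.178 with an estimated correlation). KRT14 (keratin 14) stood at 431 ± 52 against 0.421 ± 0.33, CDH1 at 1.77 ± 0.44 against 0 and KRT19 at 62.7 ± 2.2 against 0.93 ± 0.34. KRT5, the usual partner of keratin 14 and chosen after its values were seen, had no count in any library. Of single genes, TRH stood at 274 ± 53 against 0, H19 at 121 ± 15 against 0, ACAN at 92.5 ± 5 against 0, PLCXD3 at 43 ± 4.6 against 0, ENPP2 at 37.9 ± 4 against 0, OLR1 at 20.9 ± 5.8 against 0 and ITGA8 at 222 ± 17 against 0.0472 ± 0.041. Lower in Cell Applications cells were TNFRSF9 at 0.00848 ± 0.015 against 9.08 ± 0.89, CCNA1 at 0.00922 ± 0.016 against 6.08 ± 0.96, SOST (sclerostin) at 0.162 ± 0.018 against 53.5 ± 5.4, CSF2 at 0.0184 ± 0.032 against 7.22 ± 0.93 and ADAMTS18 at 0.286 ± 0.16 against 85.4 ± 5.8.

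The comparison measures how far nominally equal cells from separate sources differ. By the edgeR test, Cell Applications cells had 4318 genes higher and 3768 lower of 16207 tested, and 10 of 24 lists passed, 4 of them with an estimated correlation. The counts adjusted over the list alone were 16 higher and 1 lower for mesenchymal and pericyte surface markers and 30 higher and 4 lower for structural extracellular matrix, and those of the other lists named here were equal. Only the Cell Applications headers name a run, so whether sequencing run changed with supplier is unknown. MALAT1, a nuclear RNA, took 3.94% ± 0.295 of counts in Cell Applications and 1.31% ± 0.131 in PromoCell cells, and whether this moved calls was not tested. Other fits lost calls of lists (adjusted p), with no filter for fatty acid (0.0636); with the replicate block for matrix remodelling (0.0566) and fatty acid (0.115); with libraries thinned to the shallowest (chosen after seeing the data) for fatty acid (0.0626). Other fits lost calls of genes (adjusted p), with libraries thinned (likewise) for ADAMTS8 (0.124) and ESRRG (0.0798).

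Teratoma outgrowth carried HOX and proliferation transcripts, and embryoid body outgrowth carried neural and neural crest ones. In CPM and as teratoma against embryoid body, HOXA3 (chromosome 7, 27145809 to 27166639) stood at 21.9 ± 1.6 against 0, HOXB5 at 9.16 ± 0.99 against 0 and HOXB4 at 8.9 ± 1 against 0. The HOX genes of groups 1 to 5 were higher in teratoma outgrowth in 12 of 14 cases (adjusted p = 7.7e-09). HOX genes of groups 6 to 13 were higher in 18 of 20 cases (adjusted p = 1.32e-08). HOXC10 stood at 3.81 ± 0.72 against 0, HOXA13 at 3.04 ± 0.14 against 0 and HOXA10 at 3 ± 1.2 against 0. Cell cycle genes were higher in 30 of 30 cases (adjusted p = 5.08e-36). Log2 changes were 4.50 ± 0.23 SE for KIF20A, 4.18 ± 0.21 for CDC20 and 3.89 ± 0.27 for PLK1. Neural and neural crest markers were lower in 8 of 12 and higher in 3 (adjusted p = 0.000377). The neurotrophin receptor NGFR stood at 0.015 ± 0.026 against 68.2 ± 8.8, SOX10, a factor of neural crest and glia, at 0.0451 ± 0.078 against 38 ± 5.6, and FOXD3 at 0 against 2.12 ± 0.66.

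Heart-lineage transcription factors were higher in teratoma outgrowth in 9 of 20 cases and lower in 3 (adjusted p = 0.0181). TBX5 stood at 27.6 ± 2.1 against 0.0729 ± 0.13 and HAND2 at 9.72 ± 1.2 against 0.602 ± 0.3. Smooth muscle and myofibroblast genes were lower in 10 of 17 cases (adjusted p = 0.000113, adjusted p = 0.179 with an estimated correlation). Log2 changes were -2.06 ± 0.26 SE for LMOD1, -2.05 ± 0.12 for ACTA2 and -1.83 ± 0.23 for CTGF. Matrix remodelling genes were lower in 15 of 29 cases and higher in 3 (adjusted p = 0.00316, adjusted p = 0.0974 with an estimated correlation). PLAT stood at 42.9 ± 4.2 against 469 ± 191 and ADAMTS5 at 14.8 ± 2 against 141 ± 28, while ADAMTS2 was higher at 38.7 ± 3.7 against 0.739 ± 0.2. Cadherin and junction genes were lower in 11 of 22 cases and higher in 4 (adjusted p = 0.0092, adjusted p = 0.175 with an estimated correlation). GJA5 stood at 0 against 16.2 ± 0.94, DSC2 at 1.11 ± 0.21 against 45.3 ± 3.5 and CDH13 at 13.3 ± 1.9 against 93.9 ± 7.8. Of single genes, FOXF1, a factor of lateral mesoderm, stood at 33.6 ± 2.8 against 0, its neighbouring noncoding RNA FENDRR at 28.2 ± 4.5 against 0, HGF (hepatocyte growth factor) at 21.3 ± 1.4 against 0 and PRRX2 at 17.7 ± 1.9 against 0. In the same direction were PITX1 at 15.1 ± 2.9 against 0, ELN at 94.9 ± 14 against 0.0342 ± 0.059 and SSTR1 at 9.9 ± 2.3 against 0. Higher in embryoid body outgrowth were CDH19, a cadherin of Schwann cell precursors (chromosome 18, 64168424 to 64271375), at 0 against 76.4 ± 26, CA8 at 0 against 6.66 ± 3.9, ST8SIA2, a sialyltransferase of neural adhesion molecules, at 0.0368 ± 0.064 against 5.36 ± 1.4, CRHBP at 0.114 ± 0.14 against 24.7 ± 7.4 and PLCXD3 at 0.0835 ± 0.073 against 19.7 ± 3.1.

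The comparison sets 2 outgrowths of a single iPS line side by side. By the edgeR test, teratoma outgrowth had 3636 genes higher and 3794 lower of 16207 tested, and 8 of 24 lists passed, 5 of them with an estimated correlation. Adjusted over the list alone, the counts were 0 higher and 11 lower for smooth muscle and myofibroblast contractile genes, 3 higher and 16 lower for matrix remodelling enzymes and inhibitors and 4 higher and 12 lower for cadherins, gap junctions and desmosomes, and those of the other lists named here were equal. Fitted on these groups alone, 14 lists passed, the 8 among them. MALAT1 took 1.71% ± 0.308 of counts in teratoma and 4.3% ± 0.361 in embryoid body outgrowth. Calls of lists were lost (adjusted p) with the replicate block for heart-lineage (0.0625). Calls of genes were lost (adjusted p) with DESeq2 for CA8 (0.0714) and FOXD3 (0.268). No run is named in the headers of these libraries.

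**Figure D3:**
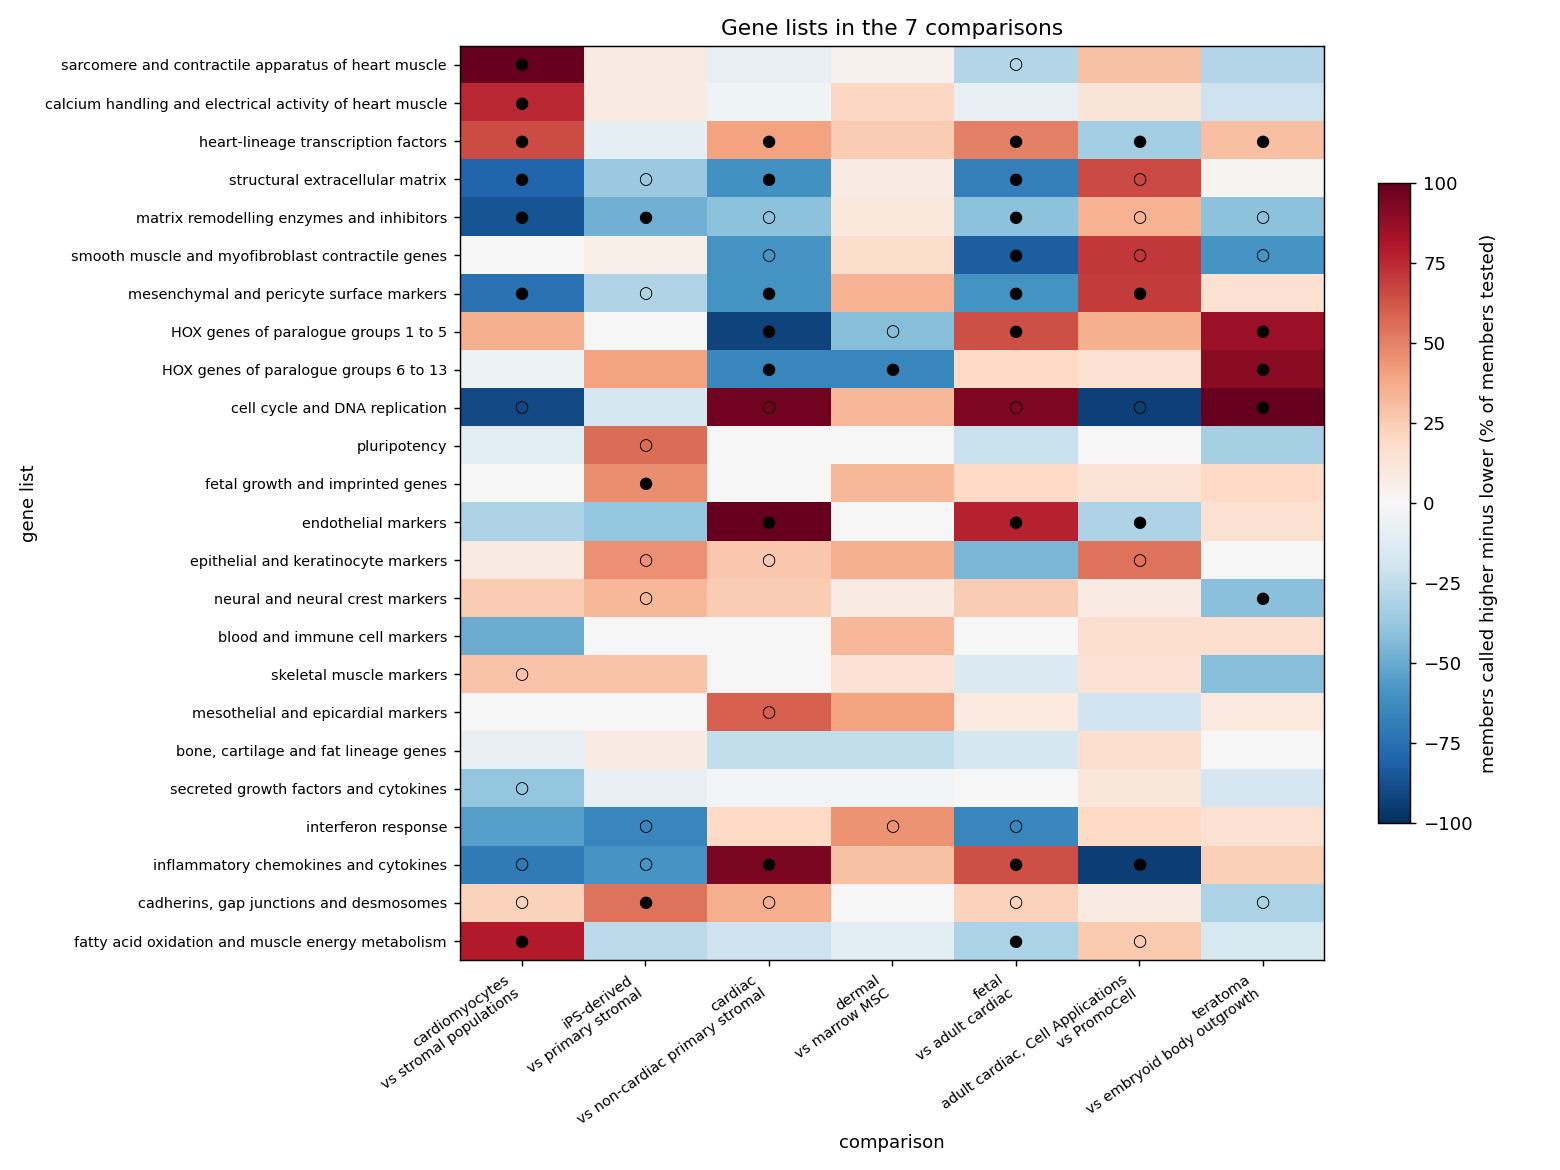
Members of each gene list called higher minus those called lower, as a percentage of the members tested, in the 7 comparisons; filled circles mark lists that passed with both the preset and an estimated correlation, open circles those that passed with the preset alone. The list of endothelial markers was higher in cardiac fibroblasts than in dermal fibroblasts and marrow MSCs (13 of 13 members) and lower in adult cardiac fibroblasts of Cell Applications than in those of PromoCell (8 of 13 members).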

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

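Replicates are not stated to be separate donors or lots, depth differs between groups, and strands were not separated in counting. Alternatives marked as added were chosen after seeing the data, and where a result changed the cause was not tested. With an estimated correlation the lists called were 7 for cardiomyocytes (12 with the preset), 3 for iPS-derived cells (10), 7 for cardiac fibroblasts (13), 1 for dermal against MSC (3), 9 for fetal (13), 4 for suppliers (10) and 5 for outgrowths (8). Fry asks another question, whether a list changed at all and not whether it changed more than other genes, and called 23, 18, 20, 19, 23, 19 and 20. For dermal against MSC, lists called were 5 with no filter, 8 with only the groups compared, 6 without dermal replicate 2 and 7 without dermal replicate 1. For the outgrowths they were 14 with only the groups compared. With each population as the replicate, iPS-derived cells had 1 gene higher and 3 lower (3247 and 3289 before), cardiac fibroblasts 0 and 1 (4345 and 3843).

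Fetal cells against PromoCell adult had 2069 genes higher, 1600 lower and 8 lists, and against the mean of both adult groups 2636 lower (before: 3979, 4066 and 13). Against PromoCell these reversed and were called, as log2 changes: ELN 1.54, MGP 1.82, CNN1 1.27, CD248 2.84, IL1A -1.66 and CSF3 -5.08. The sign changed without a call (adjusted p) for XIRP1 1.78 (0.558), CD36 2.54 (0.3), H19 2.57 (0.388), PLK1 -0.32 (0.363), CXCL6 -1.28 (0.162) and ESRRG -0.67 (0.524), and for CD248 against both adult groups, 0.14 (0.585). Called in reverse were also the inflammatory (adjusted p = 9.26e-15) and mesenchymal lists (adjusted p = 0.0132). Other reversals were ELN (1.94) and PDGFRA (0.30) for teratoma outgrowth alone against primary cells, TCF21 (-0.84) in cardiac against dermal cells only, and, without a call, HOXB5 (0.248) in cardiac cells with each population as the replicate and CDH1 (0.013) without MSC replicate 1 (with 1 library left out it ranged over -3.556 to 0.013). The distance ratio of Cell Applications adult cells (PromoCell over dermal, 1.093) was 1.141 with 500 genes. That of fetal cells (1.476) was 1.344 with prior count 0.5, 1.546 with prior count 5 and 1.752 with 500 genes.

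With 1 library left out, genes higher and lower ranged over 5244 to 6048 and 5766 to 6381 for cardiomyocytes, 2918 to 3541 and 2812 to 3530 for iPS-derived cells. They ranged over 3755 to 4501 and 3325 to 3838 for cardiac fibroblasts, 2736 to 3672 and 2694 to 3539 for dermal against MSC. Further ranges were 3033 to 3586 and 3099 to 3730 for fetal, 3757 to 3881 and 3299 to 3533 for suppliers, and 3111 to 3571 and 3198 to 3496 for outgrowths. Lists ranged over 12 to 12, 9 to 10, 12 to 13, 3 to 7, 13 to 15, 10 to 11 and 8 to 9 in that order, and the distance ratios over 1.073 to 1.096 and 1.463 to 1.487.

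Of 69 lists called, a call was lost in 103 cases and kept in 1357: 33 with estimated correlation, 12 with the replicate block, 12 thinned to the shallowest library (added), 8 with 1 library left out, 6 against PromoCell adult cardiac, 5 with no filter on low counts, 4 against the mean of both adult cardiac groups, 4 with population as the replicate, 3 with teratoma outgrowth alone, 2 with adult cardiac groups only, 2 against dermal only, 2 against marrow MSC only, 2 against teratoma and embryoid body outgrowth only, 2 with embryoid body outgrowth alone, 2 in libraries with no run named (added), 2 with only the groups compared, 1 with DESeq2 size factors (RLE) in edgeR and 1 without adult cardiac from Cell Applications (added). Of 293 results for single genes, it was lost in 150 cases and kept in 5516: 93 with population as the replicate, 18 against PromoCell adult cardiac, 11 thinned to the shallowest library (added), 8 with 1 library left out, 7 against the mean of both adult cardiac groups, 6 with DESeq2, 2 against dermal only, 2 with teratoma outgrowth alone, 1 against marrow MSC only, 1 with embryoid body outgrowth alone and 1 without adult cardiac from Cell Applications (added). The replicate block pairs libraries by number. Deviations from group means correlated between same-number libraries at -0.154 to 0.107 (median 0.002), and 8 of 22 matched their own number best.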

Other observations

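Tests for mislabelled libraries, a shared supplier and the sequencing runs of Cell Applications adult cells and cardiomyocytes were chosen after the results were seen. So were those for calls without MTRNR2L genes, absence in the whole iPS line and other groupings of whole populations.

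Marrow MSCs carried a collagen of hypertrophic cartilage. COL10A1 (type X collagen) stood at 563 ± 34 CPM in MSCs and 1.17 ± 0.4 in dermal fibroblasts, while ACAN (aggrecan) stood at 0 and 463 ± 354 and the homeobox gene MSX2 at 0.0549 ± 0.078 and 11.4 ± 5.5. As a list, bone, cartilage and fat lineage genes did not pass: 2 of 12 were higher in dermal fibroblasts and 5 lower (adjusted p = 0.0854), and no comparison called the list. The list of blood and immune cell markers passed in no comparison either (2 of 6 higher and 0 lower in dermal fibroblasts, adjusted p = 0.969), with CD68 at 53.4 ± 12 CPM in dermal fibroblasts and 25.5 ± 1 in MSCs and PTPRC (CD45) at 1.24 ± 0.46 and 0.242 ± 0.032. PTPRC was not called without MSC replicate 1 (adjusted p = 0.0934) or replicate 2 (0.0561).

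Adult cardiac fibroblasts from Cell Applications lay nearer to dermal fibroblasts than to adult cardiac fibroblasts from PromoCell. Whether a mislabelled sample is the cause, so that the libraries hold dermal cells of another source, cannot be told apart from a difference between sources. The smallest distance from a Cell Applications adult library to a dermal one was 1.28, above the largest between dermal libraries (0.789) and below the smallest between adult cardiac libraries of the 2 suppliers (1.397). GATA4, a cardiac marker chosen beforehand, ran as labelled, at 12.4 ± 0.77 CPM in Cell Applications adult cells and 0 in dermal ones. CD200 stood at 32.1 ± 1.7 and 0.0511 ± 0.045, and VIPR1, KCTD8 and CD93 at 2.19 ± 0.18, 1.75 ± 0.48 and 1.29 ± 0.087 against 0. These genes were named because every cardiac library lay above every dermal and MSC one, so cannot test the labels. WT1, at 0.402 ± 0.12 in Cell Applications adult cells and 36.3 ± 1.2 in PromoCell ones, was nearer to the dermal 0. Single genes do not exclude dermal cells of another source. An admixture of dermal cells like those sequenced could not be the whole cause, since over 46 dermal genes the level as a share of the dermal one ran from 0.392% (10th percentile) over 13.9% (median) to 132% (90th percentile), a ratio of 336 where a mixture would give a single share. Fetal cardiac libraries, which share a supplier with Cell Applications adult ones, were 1.476 times as far from these as from PromoCell ones. A common supplier did not make fetal and adult Cell Applications cells the nearer pair. This does not test a supplier shared with dermal cells, as none is given. A sequencing run cannot be told apart, as 0 dermal and PromoCell headers name one. Donor, lot, culture history or endothelial cells in PromoCell and fetal cultures were not tested.

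MTRNR2L genes, nuclear copies of mitochondrial ribosomal RNA, took 27.3% ± 4.8 of cardiomyocyte counts. Mitochondrial ribosomal RNA reads counted on these copies would raise all of them alike; the log2 ratios of the 6 copies ran from 3.28 to 4.37, a span of 1.09 against a bound of 1 written beforehand, so this and a change of the copies themselves cannot be told apart. Nor can a sequencing run or library batch, as 0 stromal headers name the run of the cardiomyocytes and 14 of 19 name none. Leaving these genes out moved few of the other calls. Without them 12056 genes were called and with them 11960. Of the 5652 higher genes 5645 were called either way, and of the 6308 lower genes 6236.

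AKR1C1, ZNF248, C11orf74, PCDHGB5, CHCHD2 and ZNF736 were at 5 CPM or more in all 5 primary stromal groups and under 0.5 in both outgrowths of the WTC11 line (AKR1C1, C11orf74 and PCDHGB5 were chosen after their values were seen). CHCHD2 and ZNF736 also had no count in cardiomyocytes of the derived line, 2 of 6 genes against 140 of 8614 (1.63%) among all genes on in the primary groups (Fisher's exact test, 1-sided p = 0.00377), which may reflect loss of expression in the whole line. The division of the 6 genes and this test were made after their levels were seen, so the p-value adds no independent support. ZNF248 (33.8 ± 5.7 CPM) and C11orf74 (51.6 ± 3.9) were on in cardiomyocytes, so absence in the whole line is excluded for them. Too few reads are excluded, as at least 669 counts were expected over the 6 outgrowth libraries.

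Random splits of single libraries were used to ask whether chance could give as many calls. Each split was tested in a fit with 1 mean per side in place of the 8 groups, so the real counts differ from those above, and counts of splits include the real one. Where a side holds several populations most splits break them up, so they do not test chance among populations. They called at most 472 genes against 9180 for cardiomyocytes, 849 against 1395 for iPS-derived cells and 2828 against 2976 for cardiac fibroblasts (1 of 100 as high in each, the real one). With other groupings of whole populations, chance is not excluded for iPS-derived cells: 10 of 21 groupings, the real one included, called as many genes, the highest 3985 (Cell Applications adult with dermal cells). For cardiac fibroblasts 10 groupings are too few for a share under 0.05 (2976 and highest other 5007, 3 as high with the real one), as are 8 for cardiomyocytes (9180 and 1270, 1 as high, the real one). For the suppliers (9000 and 0) and for the outgrowths (6582 and 0) the 10 splits are too few for a share under 0.05.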
